A study of Mus musculus with 4 samples.

How the data were processed

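DNase-seq cuts chromatin in isolated nuclei with the nuclease DNase I and sequences the cut ends, so that stretches of open chromatin appear as places dense in cuts. The samples were 4 libraries of mouse acute myeloid leukemia (AML) cells, described in the labels as differentiated in vitro and of the C57BL/6J strain. Per the labels, 2 libraries were technical replicates of biological replicate 1 and 2 were technical replicates of biological replicate 2. The labels named no treatment, time point or control, so the comparison the design allows is between the 2 biological replicates, together with a description of the sites found in both.

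Text files deposited with the samples tie each list to a biological replicate and state that the 2 libraries of a replicate share 1 alignment to the mouse assembly mm10. Each biological replicate therefore had 1 peak list and 1 hotspot list, made from its pooled libraries, and no value per library was analysed here. That the replicates were separate cultures is known only from the labels. The peak caller, its settings and the number of reads are not given in the sources used here, so depth was unknown and no interval that needs it is given. The deposited peak score, in windows of 150 bp, is a whole number that ran from 1 to 150 in replicate 1 and from 2 to 148 in replicate 2. How the authors computed that score is not given in the sources used here, and no scaling for depth is stated, so a score was used to rank or filter peaks within its own list and to describe a peak. The ranking of loci is the exception, since it sums scores as shares of the total of each list and averages both lists, which rests on that unknown scale. The deposited hotspots are wider regions with a −log10 q value in the column that the file format reserves for it. Those values started at a q of 0.05 and stopped at a ceiling of 100.

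Peaks with repeated entries at the same place, 48 in replicate 1 and 5 in replicate 2, were kept once. A peak was called shared when it overlapped a peak of the other list by at least 1 bp. The shared set holds the windows of replicate 1 that overlap a peak of replicate 2, each with the score of its strongest partner and the mean of its ranks in both lists. Overlaps were set against 100 circular shifts of 1 list along each chromosome (1-sided permutation test, smallest possible p = 0.0099), on the autosomes, X and Y. Coordinates are 1-based on mm10, whose chromosome lengths were checked against the reference sequence, and genes are from GENCODE release M21. A promoter is the stretch within 1 kb of a transcription start site (TSS) of any annotated transcript of a protein-coding gene. Starts of internal and non-coding transcripts of such a gene count too, so a promoter peak can lie far inside its gene. Among the genes named below, those of Mef2c, Mecom, Adgrg1, Myb, Lmo2, Lck, Rhd, Mmp9, Vwf, Ank1, Afp and Cd3d do. The list is not complete, and an open promoter need not be the one at the annotated start of the gene. Peaks were placed in promoter, exon, intron or intergenic sequence, in that order.

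The tests, the 21 gene lists (298 genes, all of them found in the annotation) and the 22 motifs were fixed before the data were examined. The share of members of a list with a shared peak at a promoter was compared with all other protein-coding genes on autosomes and X by Fisher's exact test, 2-sided, with Benjamini-Hochberg adjustment over the lists. Shared peaks outside promoters were counted in the gene body and 50 kb on either side, and the median over members was set against 10000 random lists matched on gene length in 20 bins (2-sided permutation test, smallest possible p = 0.0002), adjusted likewise. Motifs were exact consensus matches on either strand within 50 bp of the peak centre, compared with a window of the same width 500 bp toward the chromosome start by an exact McNemar test, 2-sided, adjusted over the motifs. Genes and peaks are the units of these tests and are not replicates, so the p-values describe these lists of sites and not the spread between cultures. Peaks outside promoters were stitched into loci at the planned distance and ranked by summed signal, each peak's mean share of the total score of its list.

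Named genes followed a rule fixed in advance: the 4 members of each list with the highest mean promoter rank, up to 3 members in alphabetical order with no promoter peak in either list, every member of the myeloid, stem cell and HOXA-MEIS lists, the 10 strongest shared peaks outside promoters and the 5 strongest at promoters, the 10 richest loci, and the 3 strongest peaks of each list without a counterpart. From these the text names part, and the values of some members are not reported here. Alternatives were a stricter score threshold, other overlap rules, other promoter and gene windows, other backgrounds, each list alone, and lists of equal length. The scripts were tested on simulated data. Lists planted with nearly all promoters open were recovered in 99.0% of simulated comparisons of promoters over 21755 genes, and 0.235% of the other lists were called. Lists planted with raised peak rates were recovered in 55.0% of simulated comparisons of peaks near genes, so that test misses part of such differences. A motif planted in simulated sequence was recovered as an excess of 2.02 percentage points over 20000 windows, and no other motif was called there. Odds ratios within strata were Mantel-Haenszel estimates. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9. Peaks on the mitochondrial genome and on unplaced scaffolds entered the counts per list and were left out of the tests of overlap, promoters, gene lists, motifs and loci.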

Results

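Open chromatin was mapped by DNase-seq in mouse acute myeloid leukemia cells, a malignancy of immature cells of the myeloid blood lineage. Each of the 2 biological replicates had 2 libraries, which the authors had pooled before calling sites, so that every value below comes from 1 list per biological replicate and carries no replicate error of its own. Replicate 1 had 236802 peaks and 202621 hotspots, which covered 88.1 Mb. Replicate 2 had 67564 peaks and 61915 hotspots, which covered 20.5 Mb. The depth of sequencing was unknown.

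The first comparison asks how far both cultures opened the same sites. Nearly all sites of the shorter list recurred in the longer one: 62000 of 67438 peaks of replicate 2 (91.9%) overlapped a peak of replicate 1, and 61768 of 236215 peaks of replicate 1 (26.1%) overlapped one of replicate 2. Hotspots gave the same picture, with 98.7% of those of replicate 2 and 26.2% of those of replicate 1 shared. Chance placement gave 2.78% for the peaks of replicate 2 and 0.792% for those of replicate 1 (permutation test, p = 0.0099 for each, the smallest that 100 shifts can give). The replicate 1 list was 3.5 times as long. Its sharing followed the score: of 10 bins of equal size, the weakest had 1.39% of its peaks shared and the strongest 93.3%. In replicate 2 the shares were 77.1% in the weakest bin and 96.9% in the strongest. Peaks of replicate 1 without a counterpart had a median score of 63, against 123 for shared ones. Across the 61881 shared peaks, which are not independent replicates, the scores of both lists had a Spearman rho of 0.794. With both lists at the length of the shorter, 70.9% of replicate 2 peaks were shared, and for peaks outside promoters rho was 0.679.

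**Figure D1:**
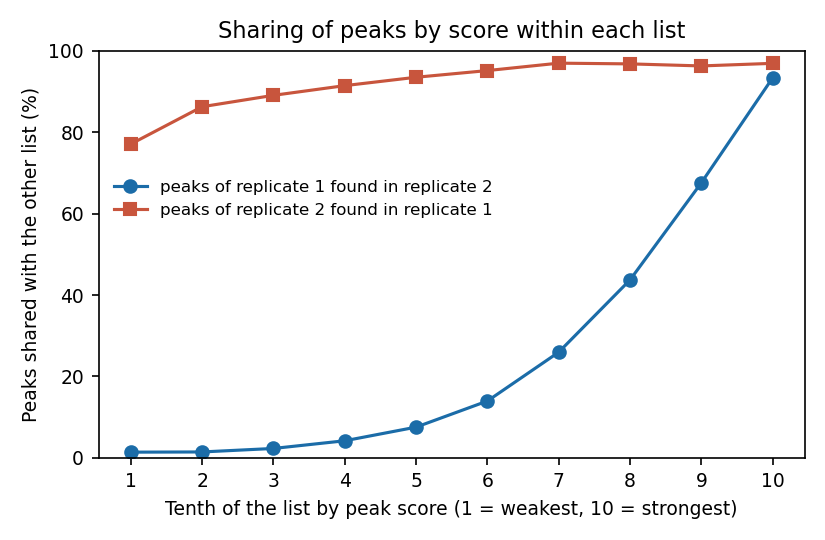
Share of peaks (%, vertical axis) that overlapped a peak of the other biological replicate, by bin of the peak score within a list (horizontal axis, 10 bins of equal size, 1 weakest, 10 strongest), with 1 line per list. The line of replicate 1 climbs from 1.39% to 93.3%, while that of replicate 2 starts at 77.1% and ends at 96.9%.

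Shared sites gathered at the starts of genes. Of the shared peaks, 31.8% lay within 1 kb of a protein-coding TSS, 7.61 times the share of shifted peaks (4.18%, permutation test, p = 0.0099). A further 4.69% lay in exons, 28.0% in introns and 35.5% between genes. The strongest promoter peaks of the shared set were those of Hjurp, a chaperone that loads the centromeric histone, Nolc1, a nucleolar protein, the heat shock protein gene Hspa8, the adducin gene Add3 and the aminopeptidase gene Lnpep. The Hjurp peak, at chromosome 1, 88277536 to 88277685, scored 150 in replicate 1 and 134 in replicate 2. Its central part holds a match to the generic ETS motif, ACTTCCGG at 88277614 to 88277621, and a C/EBP match, TTACGCAA at 88277566 to 88277573. The promoter share was 18.8% in the whole replicate 1 list and 33.6% in the replicate 2 list. It was 52.0% among the 5438 peaks of replicate 2 that overlapped no peak of replicate 1. Lacking such a peak did not always mean closed in replicate 1, since 98.8% of all replicate 2 peaks lay in a replicate 1 hotspot. That share is made up mostly of shared peaks, and the share among the unshared ones was not computed.

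The gene lists ask which cell type programmes had open promoters. Of 21755 protein-coding genes, 12658 (58.2%) had a shared peak at a promoter. All 12 myeloid transcription factors did (Fisher's exact test, adjusted p = 0.00843), among them Spi1, which encodes PU.1, Cebpa, Cebpb, Cebpd, Cebpe, Gfi1, Irf8, Klf4, Nfe2, Runx1 and Zeb2. That call ended against random lists matched on promoter GC content (permutation, adjusted p = 0.111) and with the replicate 1 list alone (exact test, 0.0633). All 12 were open in both settings, the most the list can reach, and it was the background that was higher. The median of the matched lists was 75%, and 71.1% of all coding genes were open with the replicate 1 list. The Spi1 promoter peak on chromosome 2, 91083016 to 91083165, scored 150 and 94 in replicates 1 and 2, and that of Cebpa on chromosome 7, 35119136 to 35119285, scored 148 and 97. The weakest of the group was Zeb2, with scores of 121 and 38. All 18 pan-leukocyte and myeloid receptor genes had open promoters too (exact test, adjusted p = 0.00202), among them Csf2ra and Il3ra, which encode receptor chains for GM-CSF and interleukin 3, the GTPase gene Rac2 and the actin-bundling gene Lcp1. So did all 16 housekeeping genes (exact test, adjusted p = 0.00202), including Actb, Polr2a, Ppia and Ywhaz. Of the 22 genes recurrently mutated in human AML, 20 had an open promoter (exact test, adjusted p = 0.00843), led by Smc3, U2af1, Srsf2 and Asxl1, a call that ended against lists matched on GC content (permutation, adjusted p = 0.187).

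Stem and progenitor regulators had open promoters at 15 of 18 genes (Fisher's exact test, adjusted p = 0.0747), which did not pass the test. The open members were Gata2, Tal1, Lmo2, Lyl1, Erg, Fli1, Myb, Mecom, Hhex, Gfi1b, Kit, Ikzf1, Etv6, Bmi1 and Adgrg1. Cd34 and Cd93, surface markers of progenitors, had a promoter peak in replicate 1 alone (scores 129 and 115). In the HOXA-MEIS leukemia programme 14 of 16 promoters were open (exact test, adjusted p = 0.0609), among them Hoxa7, Hoxa9, Hoxa10, Meis1, Pbx3, Mef2c, Flt3, Bcl2, Cdk6, Jmjd1c, Eya1, Sox4 and Cpeb2. Hoxa5 and Hoxa6 had a promoter peak in replicate 1 alone, with scores of 114 and 74. The Meis1 promoter peak, at chromosome 11, 19018896 to 19019045, scored 146 and 73 and holds an ETS match, CCGGAAGT, at 19018975 to 19018982. Across the Hoxa cluster on chromosome 6, replicate 1 had 82 peaks and replicate 2 had 8, all 8 of which overlapped a peak of replicate 1. The shared ones included the promoter peaks of Hoxa7 (52221816 to 52221965, scores 140 and 85), Hoxa9 (52226136 to 52226285, scores 148 and 69) and Hoxa10 (52240476 to 52240625, scores 137 and 67).

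**Figure D2:**
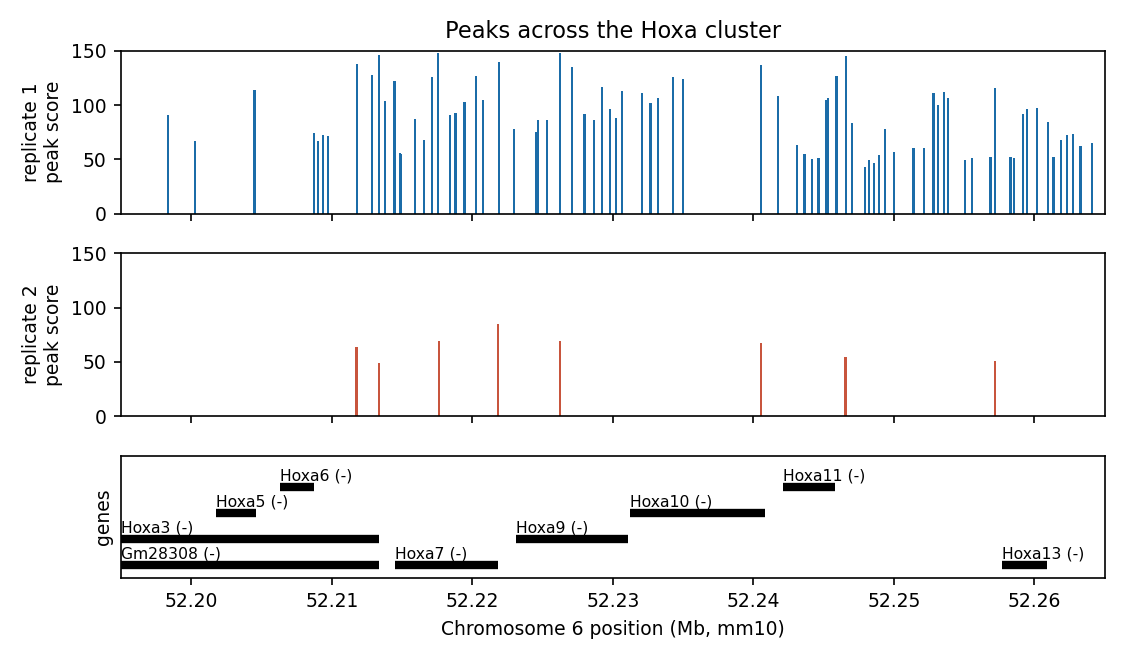
Peak score (vertical axes, no unit, 1 panel per biological replicate) against position on chromosome 6 (horizontal axis, Mb, mm10) across the Hoxa cluster, with protein-coding genes and their strands in the lowest panel. Replicate 1 had 82 peaks in the drawn region and replicate 2 had 8, each of the 8 over a peak of replicate 1.

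Differentiated myeloid genes were open in part. Neutrophil granule genes had 14 of 20 promoters open (Fisher's exact test, adjusted p = 0.385), with the highest ranks at Ncf4 (scores 150 and 63), Ctsg, Mmp9 and Ncf1. The Mmp9 peak lay at an internal start, at 164953296 of a gene that begins at 164940780 on chromosome 2. Monocyte and macrophage genes had 16 of 20 (exact test, adjusted p = 0.128), led by the scavenger receptor gene Cd68 (scores 150 and 91), Tyrobp, Fcer1g and Irf5. Every promoter of both lists that was not shared had a peak in replicate 1 alone.

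Of the lists of other cell types, 2 were open less often than other coding genes. Mast cell, basophil and eosinophil genes had 1 of 12 promoters open, that of the eosinophil peroxidase gene Epx (Fisher's exact test, adjusted p = 0.00353), while the mast cell genes Cma1 and Mcpt4 and the interleukin 5 receptor gene Il5ra had no promoter peak in either list and 6 members had one in replicate 1 alone. Hepatocyte genes had 2 of 12 (exact test, adjusted p = 0.0198), Afp and Apob, while the albumin gene Alb, Apoa1 and Cyp2e1 had none. Among blood lineages that did not pass the test, 5 of 12 B cell promoters were open (Vpreb1, Pax5, Ebf1 and Cd22 led, with none at Cd79a, Igll1 and Rag1), 5 of 15 T cell promoters (Cd3d, Lck, Tcf7 and Cd5 led, with none at Cd3g, Cd4 and Cd8a), 2 of 8 NK cell promoters (Tbx21 and Klrd1), 4 of 14 erythroid promoters (Epor, Rhd and Ank1 led) and 4 of 10 megakaryocyte promoters (Itga2b, Vwf, Itgb3 and Pf4), with adjusted p between 0.0747 for the erythroid and 0.373 for the megakaryocyte list. Endothelial, fibroblast, embryonic stem cell and muscle genes each had 4 of 12 (exact test, adjusted p = 0.184 each), epithelial genes 5 of 12 (adjusted p = 0.301) and neuronal genes 7 of 13 (adjusted p = 0.784). Among them Emcn, Tek, Col3a1, Dcn, Nanog, Dppa4, Syt1, Myh6, Krt5 and Krt14 had no promoter peak in either list. Against random lists matched on promoter GC content (permutation test), the calls also ended for mast cell (adjusted p = 0.111) and hepatocyte genes (0.138), held for pan-leukocyte (0.00420) and housekeeping genes (0.0448), and muscle genes passed as lower (0.0448). With the replicate 1 list alone (exact test), the call ended for mast cell genes (58.3%, 7 of 12, adjusted p = 0.599), while HOXA-MEIS (0.0286), neutrophil and monocyte genes (0.0136 each) passed as higher. Of all coding genes, 71.1% were open with that list. The hepatocyte share was then 33.3% and still passed. With the shared peaks above the median rank (exact test), stem and progenitor (adjusted p = 0.0414) and HOXA-MEIS genes (0.00904) passed as higher, and embryonic stem cell and epithelial (0.000560 each), NK (0.00763), erythroid (0.0121), neuronal (0.0197), endothelial, fibroblast and muscle genes (0.0279 each) passed as lower. Windows of 2.5 kb ended the calls of mast cell (exact test, 0.0579) and hepatocyte genes (0.325).

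**Figure D3:**
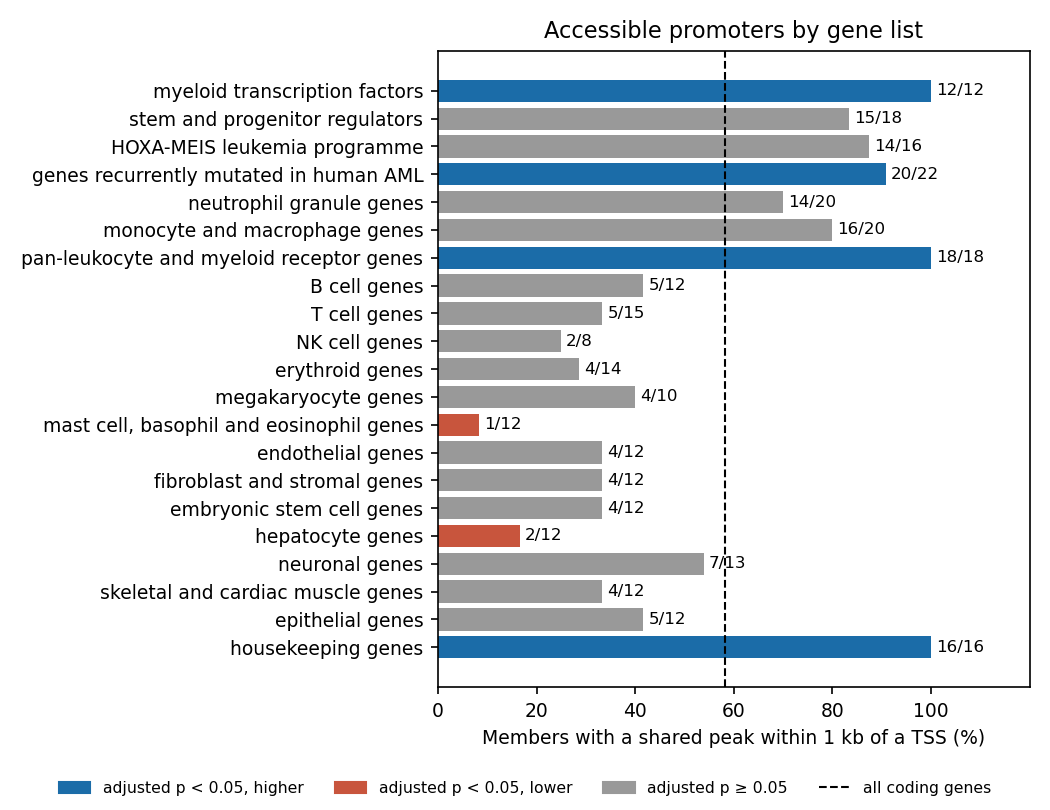
Share of members (%, horizontal axis) with a shared peak within 1 kb of a TSS, 1 bar per gene list with open members over all members at its end, the dashed line marking the 58.2% of all protein-coding genes. Blue and red bars passed Fisher's exact test after adjustment, higher for 4 lists and lower for 2, and grey bars did not.

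Sites outside promoters were dense around the genes of 3 lists. Pan-leukocyte and myeloid receptor genes had a median of 8.50 shared peaks outside promoters within 50 kb, against 3.5 in random lists of genes of the same lengths (95% range 2.00 to 5.5, adjusted p = 0.00420, permutation). Lcp1 had 13 such peaks. Stem and progenitor regulators had a median of 7.5, against 3.5 in random lists (adjusted p = 0.0168, permutation), with 22 at Erg, 20 at Etv6, 12 at Fli1, 11 each at Lyl1 and Myb, and 10 at Ikzf1. Neutrophil granule genes had a median of 6.00, against 3.00 (adjusted p = 0.0224, permutation), with 10 at Ncf4 and 9 at Mmp9. Myeloid transcription factors had a median of 5.5 (permutation, adjusted p = 0.326), with 21 peaks at Runx1, and the HOXA-MEIS programme had 4, the median of its random lists. None of the other 16 lists passed the test. The strongest peak near Fli1 outside promoters lay in an intron at chromosome 9, 32509896 to 32510045, scored 146 and 68, and holds a RUNX match, TGTGGTTT at 32509968 to 32509975, beside an E-box, GCAGCTGC at 32509999 to 32510006. The strongest near Cdk6, a cell cycle kinase gene, lay in an intron at chromosome 5, 3491316 to 3491465, scored 149 and 72, and holds an ETS match, ACTTCCGG, at 3491370 to 3491377. The call for stem and progenitor regulators ended with windows of 10 kb (permutation, adjusted p = 0.854) and that for neutrophil granule genes with windows of 100 kb (adjusted p = 0.584). With the replicate 1 list alone the called medians were 30 for pan-leukocyte, 30.5 for stem and progenitor and 24 for neutrophil genes, and the HOXA-MEIS programme (median 45, permutation, adjusted p = 0.00210), myeloid transcription factors (35, 0.00280), monocyte (25.5, 0.00840) and housekeeping genes (24.5, 0.00420) passed too. Those medians come from the longer list, and the medians of their random lists are not reported here. Myeloid transcription factors also passed within 10 kb (permutation, adjusted p = 0.0406), and they (0.0378) and housekeeping genes (0.0231) with the shared peaks above the median rank.

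The motif comparison asks which transcription factor families' sequences mark the sites outside promoters. Motifs of CTCF, of the ETS family that includes PU.1, of C/EBP, RUNX and AP-1 were all enriched at the centres of 42067 shared peaks. CTCF, which organises chromatin loops, matched 9.30% of centres and 0.0832% of flanks, a ratio of 112 (95% interval 80.1 to 156), and the ratio was 30.5 with the replicate 1 list alone. The PU.1-type ETS motif matched 6.27% of centres against 0.820% (ratio 7.65, 6.84 to 8.55), AP-1 4.66% against 1.71% (ratio 2.73), RUNX 3.56% against 1.16% (ratio 3.08) and C/EBP 0.561% against 0.0594% (ratio 9.44, 6.26 to 14.2). Of the 22 motifs, 14 were higher at centres and 4 lower after adjustment (exact McNemar test). MYB (ratio 1.89), HOX9/PBX (1.35) and MEIS (1.35) were among the higher ones, as were generic ETS (8.14), NRF1 (4, from 24 and 6 matches, and 7.8 with the replicate 2 list alone), KLF/SP (3.46), REST (3.42), NFY (1.54) and the E-box (1.51). The motifs of MEF2 (0.359), TEAD (0.655) and SOX factors (0.847) were lower, although Mef2c and Sox4 of the HOXA-MEIS list had open promoters. The Mef2c peak lay at an internal start, at 83572216 of a gene that begins at 83504034 on chromosome 13. HNF1 matched 0 centres and 6 flanks (adjusted p = 0.0382, exact), a call that ended with the shared peaks above the median rank (0.524), at equal list length (0.145), with downstream flanks (0.275) and with shuffled sequence (1.00). The SOX call ended with the replicate 1 list alone (ratio 0.979, adjusted p = 0.445, exact), where STAT5 (0.0212) and POU/OCT (0.0284) passed as lower, and GATA and STAT5 (0.0269 each) passed as lower with the replicate 2 list alone. GATA (0.860, adjusted p = 0.0746), IRF (1.09, 0.161), POU/OCT (0.944, 0.591) and STAT5 (0.952, 0.459) did not pass the exact test. Against shuffled peak sequence with the same dinucleotides, MEF2 (ratio 2.59), NFY (0.907) and MEIS (0.979) turned direction and MYB (1.06, adjusted p = 0.361, exact) no longer passed. GATA, POU/OCT and STAT5, which were not called against flanks, turned direction too, to ratios above 1.

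**Figure D4:**
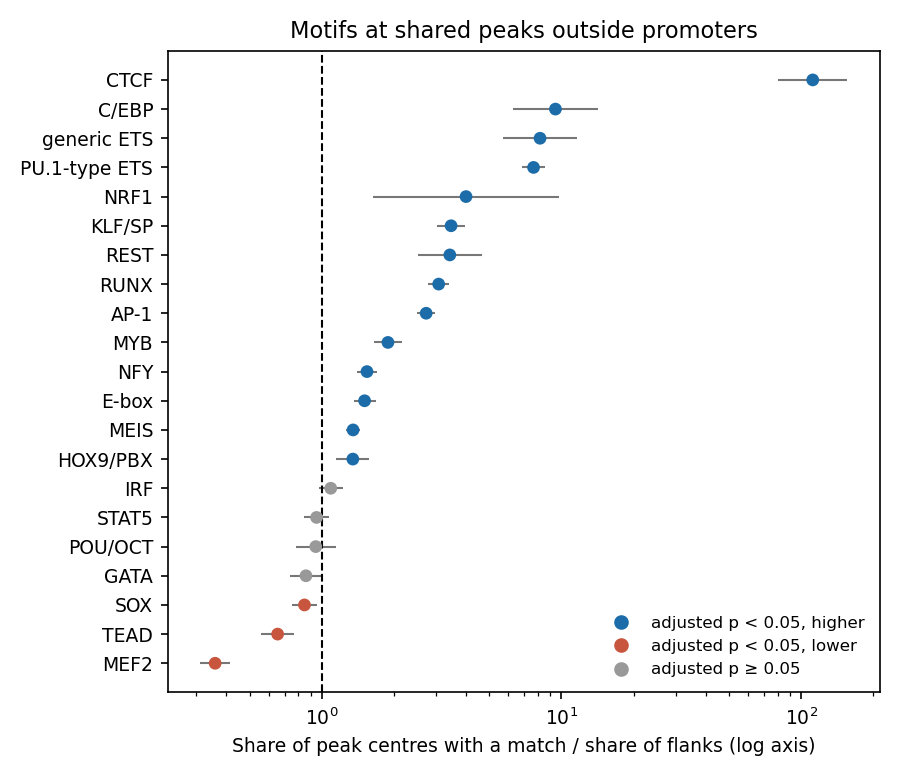
Share of centres of shared peaks outside promoters with a motif match, divided by the share of flanks (horizontal log axis), for 21 motifs with matches at centres; bars are 95% counting intervals and the dashed line marks a ratio of 1. CTCF stands at 112 (30.5 with the replicate 1 list alone), followed by C/EBP at 9.44 and the ETS motifs at 8.14 and 7.65, while MEF2 lies lowest at 0.359 (2.59 against shuffled sequence).

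Motifs at promoter peaks overlapped in part those outside promoters. Among 19645 shared promoter peaks, KLF/SP matched 14.9% of centres (ratio 4.25), NFY 8.03% (ratio 4.47), generic ETS 3.23% (ratio 8.57), CTCF 1.67% (ratio 12.2, 8.23 to 18.0), PU.1-type ETS 2.82% (ratio 3.34), C/EBP 0.387% (ratio 3.04) and AP-1 1.93% (ratio 1.81), all higher than flanks. RUNX, the E-box and HOX9/PBX, higher outside promoters, did not pass at promoters (ratios 1.10, 1.10 and 0.690, adjusted p = 0.472, 0.282 and 0.0725, exact), and GATA, not called outside promoters, was lower (ratio 0.532).

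Shared and unshared sites outside promoters differed in sequence at the same score. Among peaks of replicate 1 with scores of 80 to 99, CTCF matched 17.0% of the 7048 shared with replicate 2 and 1.14% of the 23524 found in replicate 1 alone. The PU.1-type ETS motif went the other way, at 4.11% of shared and 7.56% of unshared peaks, as did AP-1, at 2.74% and 5.82%. At scores of 140 to 150, with 285 unshared peaks, PU.1-type ETS matched 8.48% of shared and 5.26% of unshared peaks, the opposite order, and CTCF 0.550% and 0.351%. Within strata of score, the odds ratio of being shared was 17.7 for a CTCF match (95% interval 16.2 to 19.4) and 4.90 for a match to REST, a repressor of neuronal genes (3.77 to 6.36), while it was 0.621 for PU.1-type ETS (0.584 to 0.660), 0.622 for RUNX (0.574 to 0.675) and 0.529 for AP-1 (0.492 to 0.567). This comparison was chosen after the data were seen.

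**Figure D5:**
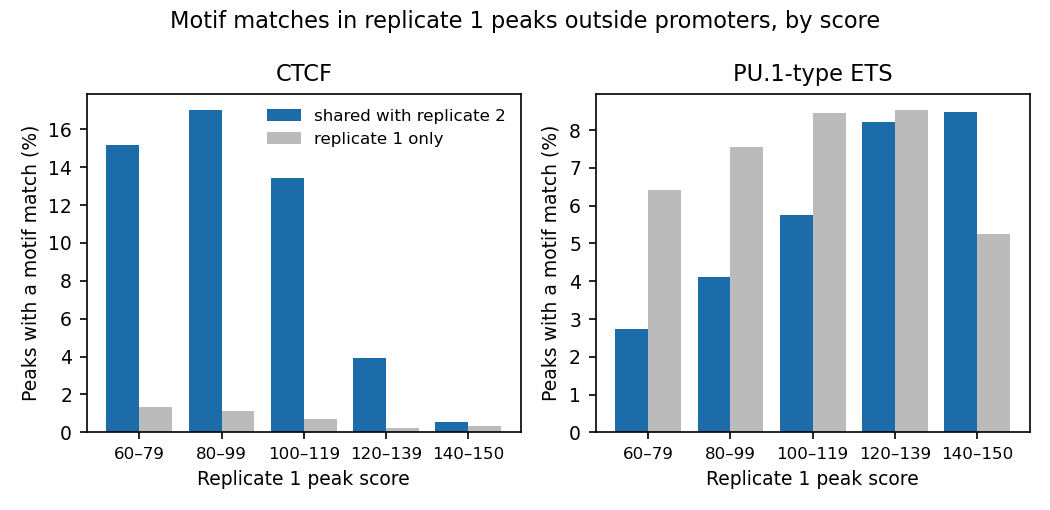
Share of replicate 1 peaks outside promoters with a match to the CTCF motif or the PU.1-type ETS motif (%, vertical axes), by range of replicate 1 peak score (horizontal axes), for peaks shared with replicate 2 (blue) and peaks of replicate 1 alone (grey). At scores of 80 to 99, CTCF matched 17.0% of shared and 1.14% of other peaks, and PU.1-type ETS 4.11% and 7.56%, an order that turned at 140 to 150 (8.48% and 5.26%).

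Loci were built only from peaks outside the promoters of protein-coding genes, so peaks at starts of noncoding genes remained in them. The loci richest in signal are listed here. The first lay in Mid1, a ubiquitin ligase gene at the end of the X chromosome (169969856 to 169999505), with 49 peaks, and the second, with 38 peaks at X, 50549896 to 50635465, covered Firre, a long noncoding RNA gene whose nearest protein-coding neighbour is the odorant receptor gene Olfr1324. Next came the immediate early gene Fosb with Rtn2 on chromosome 7 (22 peaks), a locus near Nanos3 that overlaps Zswim4 on chromosome 8 (16 peaks), the histone demethylase gene Kdm6b on chromosome 11 (18 peaks), a stretch near the chemokine receptor gene Ccr1 on chromosome 9 (16 peaks), one near Ptma on chromosome 1 (15 peaks), Gm21887 on X (10 peaks), Gdf15 on chromosome 8 (13 peaks) and the class I histocompatibility gene H2-K1 on chromosome 17 (16 peaks). In the peaks of the Mid1 cluster, 84.2% of the 36-base sequences occurred more than once in the reference chromosomes, and 99.7% in those of the Gm21887 cluster. Copies within the same cluster and on the Y chromosome were counted. The 10 strongest single peaks outside promoters included 1 in an intron within the Mid1 cluster, 1 in an intron of Gm21887, and peaks nearest to Aida, Zfp395, Fbrs, Tex44, Cct8l1, Fos, Rabepk and Aacs. The peak near Fos lay 11.1 kb downstream of its TSS at chromosome 12, 85485936 to 85486085, with scores of 150 and 103.

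The strongest peaks without a counterpart in the other list are given here. Those of replicate 1 were taken in sorted order from a tie, so their places do not describe the tied peaks as a group. In replicate 1 they lay at the promoters of Cul3, Actr3 and the interferon gamma receptor gene Ifngr1, the first of 56 unshared peaks tied at a score of 150. In replicate 2 they lay on an unplaced scaffold (score 148), on the mitochondrial genome (score 143) and in an intron near Gm21887, within the cluster at Mid1 (X, 169997076 to 169997225, score 138).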

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

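No test was run on these counts, and no explanation of them was tested. Peaks also lay outside the chromosomes that the comparisons used, and with no control sample any such peak lies above a count of 0. On the mitochondrial genome there were 22 peaks in replicate 1 and 10 in replicate 2. On the unplaced and unlocalized scaffolds there were 519 in replicate 1 and 111 in replicate 2.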

How the results depend on the processing

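The settings with the replicate 1 list reduced to the length of the replicate 2 list, and loci on autosomes only, were chosen after seeing the data, while the other settings were planned. Sharing of replicate 2 peaks stayed above the shifted shares in all 5 alternatives (70.9% to 98.7%), and the promoter share in all 7 (18.8% to 46.4%). Spearman's rho was 0.729 at the length of the shorter list and 0.679 outside promoters. Of the loci, 7 to 8 of 10 recurred under each alternative.

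The number of lists called at promoters went from 6 to 16 with the shared peaks above the median rank, 13 at equal list length, 10 with windows of 500 bp and 3 against lists matched on GC content. For peaks near genes the 3 calls became 5 above the median rank, and 3 to 7 with 1 replicate left out, the 7 without replicate 2. Called promoter lists kept their call in 34 of 42 comparisons, lists of peaks near genes in 19 of 21, and motifs in 116 of 126, where 3 reversed. Motif calls numbered 16 to 20.

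Direction reversed as follows, and the cause was not tested. With 1 replicate left out, open promoters ranged from 41.7% to 75% for B cell, 33.3% to 73.3% for T cell, 40% to 80% for megakaryocyte, 33.3% to 75% for fibroblast and 53.8% to 84.6% for neuronal genes. Each lower share came from the replicate 2 list alone, where 58.8% of all coding genes were open. Each higher one came from the replicate 1 list alone, where 71.1% were. The medians near genes below come without those of their random lists. Median peaks near genes ranged from 4 to 20.5 for genes mutated in AML, 2 to 16 for mast cell and 4 to 13 for muscle genes, and motif ratios from 0.98 to 1.04 for IRF and 0.830 to 1.06 for GATA. With windows of 2.5 kb, 92.3% of neuronal promoters were open. Median peaks near genes were 1 for mast cell genes above the median rank, 2 for NK and for mast cell genes at equal length, and 7 for neuronal genes within 100 kb. Within 10 kb they were 1 for genes mutated in AML, 0 for megakaryocyte, 1.5 for endothelial and 1 for hepatocyte genes. Matched also on TSSs they were 4 for HOXA-MEIS, 4 for genes mutated in AML and 3 for hepatocyte genes. The motif ratio was 1.32 for POU/OCT above the median rank and 1.05 at equal length, and 1.07 for STAT5 within 75 bp. Against shuffled sequence it was 1.43 for GATA, 0.907 for NFY, 1.94 for POU/OCT, 2.59 for MEF2, 0.979 for MEIS and 1.68 for STAT5. Depth was unknown, so what it limits was not computed.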

Other observations

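The tests of the threshold, of GC content, of PU.1-type sites and of repeated sequence were chosen after the result was seen, as were the looks at windows, the Y chromosome, Xist and the immediate early genes. The criteria for the threshold and for PU.1-type sites were made stricter after their values were seen.

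The replicate 1 list was 3.5 times as long as the replicate 2 list. Fewer of the same sites passing the threshold in replicate 2 cannot be told apart from other causes. Of replicate 2 peaks 98.8% lay in a replicate 1 hotspot, which the sharing of the lists had already shown, while at equal list length 70.9% were shared. Different cell types in the cultures cannot be told apart from like ones. At equal list length, members of the 13 lists of other cell types had an odds ratio of 1.47 for being open in replicate 2 alone (95% interval 0.592 to 4.17, Fisher's exact test, p = 0.419), an interval left wide by 20 and 7 such members. The pooled lists went both ways. Members open in replicate 2 alone and in replicate 1 alone were 4 and 0 for neuronal, 4 and 0 for epithelial, 0 and 3 for T cell and 1 and 3 for mast cell genes. Outside the 13, neutrophil granule genes had 0 and 4, and stem and progenitor regulators 0 and 2. HOXA-MEIS genes and genes mutated in AML had 0 and 1 each, and monocyte genes 1 and 1. No list passed on its own (binomial test against even odds, smallest adjusted p = 0.875). Even odds were not the background, since 754 coding genes were open in replicate 2 alone and 386 in replicate 1 alone. No single list was tested against that background. Sequencing depth, not given in the sources used here, and a difference between the cultures stay open.

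Sites with a CTCF match were shared far more often than others of the same replicate 1 score. The tables argue against GC content as the whole cause, since the odds ratio was 16.9 within strata of score and GC content and 17.7 within strata of score alone. Fewer open myeloid-type sites in the cells of replicate 2 cannot be told apart from other causes. Without CTCF-match peaks, a PU.1-type match had an odds ratio of 0.694 for being shared (0.652 to 0.738), which restates the lower sharing already seen. Motifs of other factors were mixed, with 0.677 for MEF2, 0.693 for GATA and 0.861 for SOX, but 1.00 for TEAD (0.826 to 1.22) and 0.910 for POU/OCT (0.734 to 1.13). Of the motifs counted as myeloid, RUNX had 0.688 (0.634 to 0.747) and C/EBP 0.894 (0.726 to 1.10). With GC content also in the strata and CTCF-match peaks kept, PU.1-type was at 0.617 (0.58 to 0.656), RUNX at 0.697 (0.642 to 0.756) and C/EBP at 0.898 (0.729 to 1.11). GATA was at 0.743 (0.627 to 0.880) and HOX9/PBX at 0.728 (0.621 to 0.853). MEF2 at 0.875 (0.729 to 1.05), SOX at 0.921 (0.811 to 1.05), TEAD at 1.12 (0.931 to 1.35) and POU/OCT at 1.03 (0.832 to 1.26) had intervals that include 1. Myeloid and other motifs were thus not cleanly separated, since the C/EBP interval includes 1 and those of GATA and HOX9/PBX do not. A score that understates sites with a narrow open window cannot be told apart from other causes. It predicts that CTCF-match peaks lie more often in hotspots at the q ceiling, as they did (odds ratio 4.31, 3.86 to 4.81). It also predicts narrower hotspots, found at scores of 80 to 99 (median 360 against 394 bp) and 100 to 119 (496 against 557 bp). At 60 to 79 their hotspots were not narrower (282 against 280 bp). The difference in list length above stays open as a cause too.

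The clusters at Mid1 and Firre were the richest in signal. Of the 36-base sequences of the Mid1 cluster 84.2% recur in the reference, with a median of 2 copies, against 1.97% for other peaks outside promoters. Sequence present in several copies may thus play a part there. Copies on Y and within the cluster were counted, so recurrence does not show that copies raised its signal. For the Firre cluster, sequence in several copies cannot be told apart from other causes, since 11.9% recur, between the bounds set for the test. No biological explanation was tested for either.

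Windows of 1 Mb were compared by an exact binomial test that takes each peak of either list as an independent draw. Most peaks of replicate 2 overlap one of replicate 1, so its calls describe the lists and not a difference between the cultures. Of 2100 windows with at least 10 peaks, 32 differed between the lists after adjustment, 18 with fewer peaks in replicate 2 than its share of all peaks and 14 with more. The first was chromosome 1, 173 to 174 Mb, with 166 and 10 peaks, followed by chromosome 3, 3 to 4 Mb, with 73 and 0, and by X, 169 to 170 Mb, which holds the Mid1 cluster and went the other way, with 134 and 83 peaks against 48.2 expected in replicate 2. On the Y chromosome 77 of 106 peaks of replicate 1 and 36 of 43 of replicate 2 lay beyond 90 Mb, and no promoter peak was found at Ddx3y, Uty, Kdm5d or Eif2s3y. Whether the sequence beyond 90 Mb also occurs on X was not tested, so these counts do not show which chromosome the reads came from. Xist had 3 promoter peaks in replicate 1 and 1 in replicate 2, with top scores of 121 and 43. The immediate early genes Fos, Fosb, Jun, Junb, Egr1 and Ier2 had promoter peaks in both lists, with top scores from 147 to 150 in replicate 1 and from 95 to 103 in replicate 2.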
